A study of Mus musculus with 20 samples.

How the data were processed

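Mouse embryonic stem cells of a 129 background, either wild-type (WT) or lacking thymine DNA glycosylase (TDG KO), were grown on mitotically arrested embryonic fibroblasts in medium with serum and LIF, per the labels' protocols, and fibroblasts were depleted by repeated plating. RNA-seq of polyadenylated RNA covered 2 libraries per genotype, and chromatin immunoprecipitation of CTCF with sequencing (ChIP-seq) covered 2 libraries per genotype. RNA polymerase II, IgG and input libraries of the series were not analysed here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each genotype may be a single cell line, so a difference between the genotypes is also a difference between the lines used.

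For RNA, the deposited table holds FPKM values (fragments per kilobase of transcript, scaled by the mapped fragments) of 46939 genes in each library, per the file headers. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff with the mm10 genome build, without their roles or order. The authors' deposited table of the comparison holds mean FPKM, log2 folds, a test score, p-values and q-values. Its log2 fold was WT over TDG KO in 16170 of the 16171 genes checked, so its sign was turned here. The authors' means equalled the means of the libraries in 46937 genes, within a relative tolerance of 0.001. The deposited FPKM table holds no counts, so absolute depth is unknown. The steps between low values put the depth relative to WT replicate 1 at 0.856 for WT replicate 2, 0.99 for TDG KO replicate 1 and 0.93 for TDG KO replicate 2. A library had between 20537 and 21776 genes above 0. Strand use in the authors' counting is not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical gene copies, are uncertain.

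For CTCF, the authors deposited a separate peak list for each library, with a score per peak. What the score measures, the control library and the peak threshold are not given in the sources used here. The score was used only to rank or filter peaks inside its own list. The submitters' processing notes name Bowtie2 2.2.9, MACS2 2.2.1 and deepTools with mm10. Read depth of the CTCF libraries is unknown, and lists of different length can follow depth or enrichment as well as binding.

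Expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the trend option and Benjamini-Hochberg adjustment over the 12035 genes with a mean FPKM of at least 1, at a threshold of 0.05. Fold changes on this scale understate the change of low genes. All tests were 2-sided. The test was checked on simulated data of the same 12035 genes for the comparison of TDG KO with WT. Of 100 genes changed by 0.5 log2 33% were called, and of 100 genes changed by 1 log2 76%. Of 11835 unchanged genes 3 were called. The simulation shuffled the spreads over genes and changed only 200 genes, all among the more highly expressed. In the data 54% of genes were called, so these rates may not carry over to the comparison. Gene lists were tested with camera at a preset correlation of 0.01, and also with an estimated correlation. Adjustment was over the lists that had at least 3 tested members. With an estimated correlation camera rests on the 2 residual degrees of freedom of the design. It could then hardly call any list, so a call missing there decides little. The 19 lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Exceptions are the tests and alternatives said below to have been chosen after seeing the data. The rule named Tdg, the 12 highest and 12 lowest called genes with a mean FPKM of at least 5 whose groups did not overlap, up to 4 called members of each list (or 2 if none was called), the 3 best-ranked regions of each class of CTCF region, the regions within 10 kb of 21 loci, and the 3 highest and 3 lowest called genes near TDG KO-only regions.

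CTCF peaks of the 4 lists were merged where they overlapped by at least 1 bp. A region with peaks in both TDG KO lists and neither WT list was called TDG KO-only, the reverse WT-only, and a region with peaks in all 4 lists shared. The procedure was tested on simulated lists, in which 3950 of 3950 planted regions were put in their class. Confidence intervals are exact 95% binomial intervals and cover counting error only. A comparison of 2 with 2 libraries cannot go below p = 0.33 in an exact permutation test, so counts of peaks carry no p-value. Coordinates are mm10, 1-based, and gene positions come from the RefSeq table of the same build, which matched 11850 of the 12035 tested genes (98.5%). That table gives gene ends without strand or exons. Distances are therefore to either end of a gene where the plan named a transcription start, and exons and introns were not told apart. The planned comparison of CTCF motifs needs the genome sequence, which was not used here, and it was not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

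A rule for windows was chosen after seeing the data. The genome was divided into windows of 10 Mb, and a window was named shifted where it held at least 200 peaks, its share of the peaks differed by at least 0.2 on the log2 scale between the genotypes after centring on the median window, and the libraries of the 2 genotypes did not overlap. The rule uses peaks alone, but its limits were set with the RNA change of the windows already in view and after other limits had been looked at. All 15 combinations of 5 log2 limits with 3 minimum numbers of peaks were therefore run. Their range is given for region counts, called genes and the RNA direction off chromosome 11. Gene lists and genes near CTCF regions were run outside the windows under the rule used only.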

Results

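The series compared WT and TDG KO mouse embryonic stem cells. TDG is the glycosylase that removes the oxidised cytosines 5-formylcytosine and 5-carboxylcytosine from DNA, and the series title asks how 5-carboxylcytosine bears on the binding of CTCF, a zinc finger protein that organises chromatin loops, to weak sites. RNA was measured in 2 WT and 2 TDG KO libraries and CTCF binding in 2 WT and 2 TDG KO libraries. Replicate RNA libraries correlated across genes at r = 0.989 in each genotype, and libraries of different genotype at 0.955 to 0.96. Genes are not independent replicates in these correlations.

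Tdg RNA (ENSMUSG00000034674, chromosome 10, 82629814 to 82650799) was lower in both TDG KO libraries. WT replicates 1 and 2 held 28.1 and 30.4 FPKM and TDG KO replicates 1 and 2 held 5.50 and 4.74 FPKM. The log2 change was -2.31 (SE 0.087, limma with Benjamini-Hochberg adjustment, adjusted p = 9.21e-06). Remaining Tdg RNA of 5.12 ± 0.538 FPKM (SD, n = 2) does not tell which part of the gene it came from.

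The comparison of RNA asks which genes differ between cells with and without TDG. Among the genes that rose furthest in TDG KO were Dppa3, a maternal factor that guards DNA methylation in the early embryo, Rhox5, a homeobox gene of the X chromosome, and Tuba3a, a testis tubulin. Dppa3 went from 1.75 ± 0.108 to 59.9 ± 2.89 FPKM, Rhox5 from 25.3 ± 3.21 to 527 ± 19.9 FPKM, and Tuba3a from 12.2 ± 0.419 to 198 ± 6.50 FPKM (mean ± SD, n = 2). Grb10, an imprinted adaptor of insulin receptor signalling, fell from 77.2 ± 2.69 to 16.6 ± 0.412 FPKM, and Pdha1, a subunit of pyruvate dehydrogenase, fell from 613 ± 20.9 to 109 ± 0.458 FPKM. In all, limma called 6496 of 12035 genes at an adjusted p under 0.05, 2942 higher and 3554 lower in TDG KO. The excess of lower calls turned with no filter on FPKM (3345 higher and 2886 lower) and nearly vanished with upper-quartile scaling (3143 and 3165). Of the 6496, 592 also changed by at least 1 on the log2 scale, 435 higher and 157 lower. The groups did not overlap in 78.8% of the tested genes, where chance gives 33.3%.

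Further genes at the top were Xlr3a (log2 change 4.64), Xlr3b (3.59), Pnma5 (3.94), Usp26 (3.23), Gm9 (3.70), 1700013H16Rik (4.14), 1700019B21Rik (3.85) and Tmem40 (3.54). Of the 12 highest genes, 8 lie on the X chromosome and 3 on chromosome 6, and Xlr3a and Xlr3b are close copies whose reads may be shared. Hsp90ab1, a heat shock protein that all cells use, is listed at 0 in both WT libraries and at 2631 and 2743 FPKM in the TDG KO libraries, and the authors' deposited table marks it as too deep to estimate, so no fold is given. Dppa3, Tuba3a and Tmem40 lie in windows of chromosome 6, and Rhox5 and Gm9 in a window of the X chromosome, where the share of CTCF peaks was also higher in TDG KO.

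Among the genes that fell furthest were Phka2, a regulatory subunit of phosphorylase kinase (log2 change -2.57), Atp2a3, a calcium pump (-2.54), Pdha1 (-2.48), Piga, needed for the first step of GPI anchor synthesis (-2.11), A830080D01Rik (123 ± 2.96 to 14.6 ± 2.13 FPKM, SD, n = 2) and Gm9855 (-2.24). Phka2, Pdha1, Piga and A830080D01Rik lie in windows of the distal X chromosome where the share of CTCF peaks was also lower in TDG KO. WT replicate 1 stood apart there: from 150 to 160 Mb the lists held 379 and 109 peaks in WT replicates 1 and 2 and 94 and 105 in TDG KO, and from 160 to 170 Mb 476 and 141 in WT and 72 and 94 in TDG KO. Without WT replicate 1 the log2 differences went from -1.64 to -0.51 and from -2.24 to -1.14, a check chosen after seeing the data. Mir1957b is listed at 54.0 and 89.4 FPKM in WT and at 0 in both TDG KO libraries. Gm28625 (-3.26), Gm24289 (-2.43) and Snora15 (-2.85) completed the 12 with Tdg and Grb10. Mir1957b, Gm24289 and Snora15 are short RNAs that a polyadenylated library measures poorly, and the call of Snora15 was lost without WT replicate 1 (adjusted p = 0.0674) and without WT replicate 2 (adjusted p = 0.132) in limma. With no filter on FPKM, Snora15 had an adjusted p of 0.168 and Gm24289 of 0.0956.

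**Figure D1:**
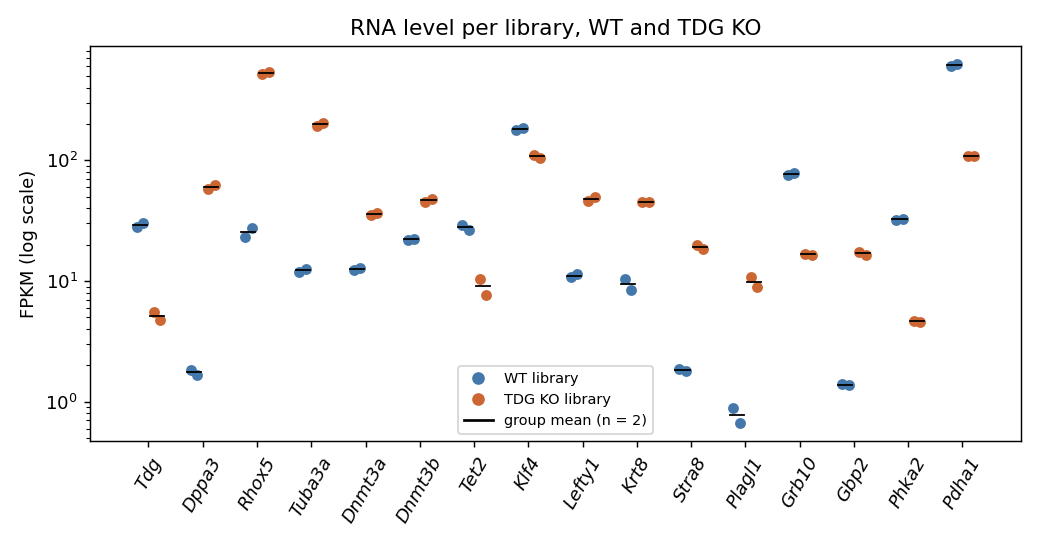
Each point is the FPKM of a library on a log axis for 16 of the named genes, WT in blue and TDG KO in orange, and bars are group means of 2 libraries. Tdg lies at 28.1 and 30.4 FPKM in WT and at 5.50 and 4.74 FPKM in TDG KO.

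Genes of DNA methylation and demethylation moved both ways. Dnmt3a and Dnmt3b, which set new methylation, rose by 1.44 and 1.05 on the log2 scale, and Tet2, which oxidises 5-methylcytosine, fell by 1.53. Of 23 tested members 8 rose, 8 fell and 7 were not called, with the same 8 and 8 when adjusted over the list alone, and camera did not set the list apart from other genes (adjusted p = 0.482). In base excision repair, the pathway TDG feeds, 5 of 20 tested genes rose and 9 fell, also adjusted over the list alone, and camera gave an adjusted p of 0.593. Mpg, a glycosylase for alkylated bases, rose by 0.83 and Lig3, a DNA ligase, by 0.71. The endonuclease Apex1 fell by 0.72 and Parp2 by 0.56. Of the 5 risers, Mpg and Lig3 lie in windows of chromosome 11 and Ogg1 and Mbd4 in windows of chromosome 6 with a higher share of CTCF peaks, and outside the shifted windows 1 of 15 tested genes rose and 9 fell.

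Of 22 tested genes of CTCF and cohesin, the ring complex that CTCF stops on DNA, 13 fell and 3 rose (14 and 3 when adjusted over the list alone). Hdac8, a deacetylase of cohesin, fell by 0.82 and Nipbl, its loader, by 0.67. The risers included Smc1b, a meiotic cohesin subunit (log2 change 2.16), and Ctcfl, the germline relative of Ctcf (1.29). The list was lower by camera (adjusted p = 0.0318), but not with an estimated correlation (adjusted p = 0.612), without WT replicate 2 (adjusted p = 0.0716) or without the shifted windows (adjusted p = 0.101), an alternative chosen after seeing the data, under which the median log2 change stayed at -0.29 and 12 of 21 genes were lower.

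Naive pluripotency genes split, with 10 of 29 tested members higher and 13 lower, also adjusted over the list alone. Tfcp2l1 fell by 1.16 and Klf4 by 0.75, both factors of the naive state, whereas Pecam1, a surface adhesion protein, rose by 0.95, and Dppa3 is also in this list. Pecam1 and Dppa3 lie in shifted windows, outside which 6 of 24 rose and 13 fell. The median of the list was -0.18 and the mean 0.04, and camera gave an adjusted p of 0.587 downwards. Genes of the primed epiblast, the later state, rose in 13 and fell in 4 of 17 tested members, also adjusted over the list alone. Lefty1, an inhibitor of Nodal, rose by 2.01, the growth factor Fgf8 by 1.82, the mesoderm factor T by 1.80 and the keratin Krt18 by 1.74. Camera called the list higher (adjusted p = 0.0013), and not with an estimated correlation (adjusted p = 0.449).

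All 8 tested neural and ectoderm genes rose, also adjusted over the list alone, among them Tubb3, a neuronal tubulin (log2 change 1.90), Nes, an intermediate filament of neural progenitors (1.68), Nefl, a neurofilament (1.59), and Krt8, a keratin of simple epithelia that is also in the trophectoderm list (2.14). The list was higher by camera (adjusted p = 3.11e-05), but not with an estimated correlation (adjusted p = 0.449 with an estimated correlation). In the trophectoderm list 9 of 14 rose and 3 fell (10 and 3 adjusted over the list alone), with Peg10 (2.02), Rhox9 (1.97) and Rhox6 (1.80) among the risers, at an adjusted p of 0.00709 in camera and an adjusted p = 0.449 with an estimated correlation. Rhox6 and Rhox9 share the X chromosome window with Rhox5. In mesoderm and endoderm 4 of 9 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.593). T rose by 1.80 and Eomes, another T-box factor, fell by 0.64. Sparc (0.49) and Lama1 (0.33) were called, but Sparc not without either TDG KO replicate (adjusted p = 0.0593 and 0.0882 in limma), and Lama1 not without WT replicate 1, WT replicate 2 or TDG KO replicate 1 (adjusted p = 0.0593, 0.115 and 0.109). With no filter on FPKM neither was called (Sparc adjusted p = 0.062, Lama1 adjusted p = 0.0843).

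Germline genes rose in 17 and fell in 7 of 28 tested members (19 and 7 adjusted over the list alone). Besides Tuba3a these included Stra8, the gatekeeper of meiosis (log2 change 2.84), Tuba3b (2.67) and Fkbp6 (2.32), and Tuba3a and Tuba3b are close copies. By camera the germline list was higher (adjusted p = 0.0013), with an adjusted p = 0.612 with an estimated correlation. In the 2-cell-like list, genes of the totipotent-like state, 8 of 10 rose and 0 fell, also adjusted over the list alone. Pramel7 rose by 2.57, Pramel6 by 2.54, Usp17lb by 1.43 and Usp17le by 1.13, all members of families of close copies. This list was also higher by camera (adjusted p = 0.000243), with an adjusted p = 0.449 with an estimated correlation.

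Imprinted genes, expressed from a single parental copy, rose in 13 and fell in 7 of 30 tested members (14 and 7 adjusted over the list alone). Plagl1, a zinc finger regulator of an imprinted network, rose from 0.772 ± 0.157 to 9.89 ± 1.33 FPKM, Peg10 from 21.0 ± 0.080 to 88.5 ± 8.44 FPKM and Nnat from 4.89 ± 0.496 to 17.9 ± 0.744 FPKM (SD, n = 2), whereas Dcn, also a fibroblast marker, was among the fallers, and Grb10 fell although it lies on chromosome 11, where most genes were higher. Imprinted genes were higher by camera (adjusted p = 0.0361), with an adjusted p = 0.449 with an estimated correlation. The call was also lost without WT replicate 2 (adjusted p = 0.185), without TDG KO replicate 1 (0.0614), with no filter on FPKM (0.0604) and at a mean FPKM of at least 5 (0.0517).

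Interferon response genes rose in 12 and fell in 3 of 25 tested members, also adjusted over the list alone, led by Gbp2, a guanylate-binding protein (log2 change 2.91), Bst2, which tethers virus particles (2.22), Psmb8, a subunit of the immunoproteasome (2.09), and the chemokine Cxcl10 (1.74). The interferon list was higher by camera (adjusted p = 0.0054), with an adjusted p = 0.449 with an estimated correlation. That call was also lost with no filter on FPKM (adjusted p = 0.0542) and at a mean FPKM of at least 5 (0.0756). In glycolysis and hypoxia 12 of 28 rose and 2 fell, also adjusted over the list alone, with the glucose transporter Slc2a1 (0.87), P4ha2 (0.77), Tpi1 (0.71) and Aldoc (0.70). Higher too by camera was this list (adjusted p = 0.022), with an adjusted p = 0.612 with an estimated correlation, and P4ha2, Tpi1 and Aldoc lie in shifted windows, outside which 7 of 22 rose and 2 fell. Of 26 tested p53 targets 3 rose and 12 fell (4 and 12 adjusted over the list alone), at an adjusted p of 0.201 in camera. The kinase Plk3 rose by 1.34, and Trp53inp1, Phlda3 and Eda2r fell by 0.93, 0.85 and 0.83.

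The 3 tested members of the Y-linked list rose, also adjusted over the list alone, and of all 5 tested genes placed on the Y chromosome 4 were called higher and 1 lower. The RNA helicase Ddx3y went from 0.604 ± 0.054 to 12.8 ± 0.987 FPKM, Uty, a histone demethylase relative, from 0.082 ± 0.058 to 3.60 ± 0.598 FPKM and Eif2s3y, a translation factor, from 8.16 ± 0.493 to 34.3 ± 0.677 FPKM (SD, n = 2). As a list they were higher by camera (adjusted p = 0.00133), with an adjusted p = 0.449 with an estimated correlation. CTCF peaks on the Y chromosome below 90 Mb were also fewer in WT (2 and 2) than in TDG KO (31 and 55). A difference between the lines over the Y chromosome cannot be told apart from a response of these genes to loss of TDG. Hoxc13 and Hoxb9, the 2 tested Hox genes, fell by 0.93 and 0.46, also adjusted over the list alone. Of 4 tested protocadherins 1 rose, also adjusted over the list alone, a gene listed as Pcdhga8 (0.32), and camera gave an adjusted p of 0.597. Rlim, the tested gene of X inactivation, was at 25.2 FPKM in each genotype and was not called (adjusted p = 0.954 in limma), also adjusted over the list alone.

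Markers of fibroblasts, the feeder cells of the cultures, fell in 16 and rose in 2 of 28 tested members, also adjusted over the list alone. Col3a1, a fibrillar collagen, went from 43.5 ± 19.4 FPKM (57.1 in WT replicate 1 and 29.8 in WT replicate 2) to 17.2 ± 2.60 FPKM (SD, n = 2). The proteoglycan gene Dcn fell by 1.19, S100a4 by 1.09 and the collagen Col6a3 by 0.92. All 28 markers were higher in WT replicate 1 than in WT replicate 2. Camera called the markers lower (adjusted p = 0.00974), with an adjusted p = 0.717 with an estimated correlation, which was 0.904. The call was lost without TDG KO replicate 1 (adjusted p = 0.066) and at a mean FPKM of at least 5 (0.0517). Col3a1 was not called without TDG KO replicate 1 (adjusted p = 0.0987 in limma), without TDG KO replicate 2 (0.0616) or with no filter on FPKM (0.069), and Dcn not without TDG KO replicate 2 (0.0532).

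**Figure D2:**
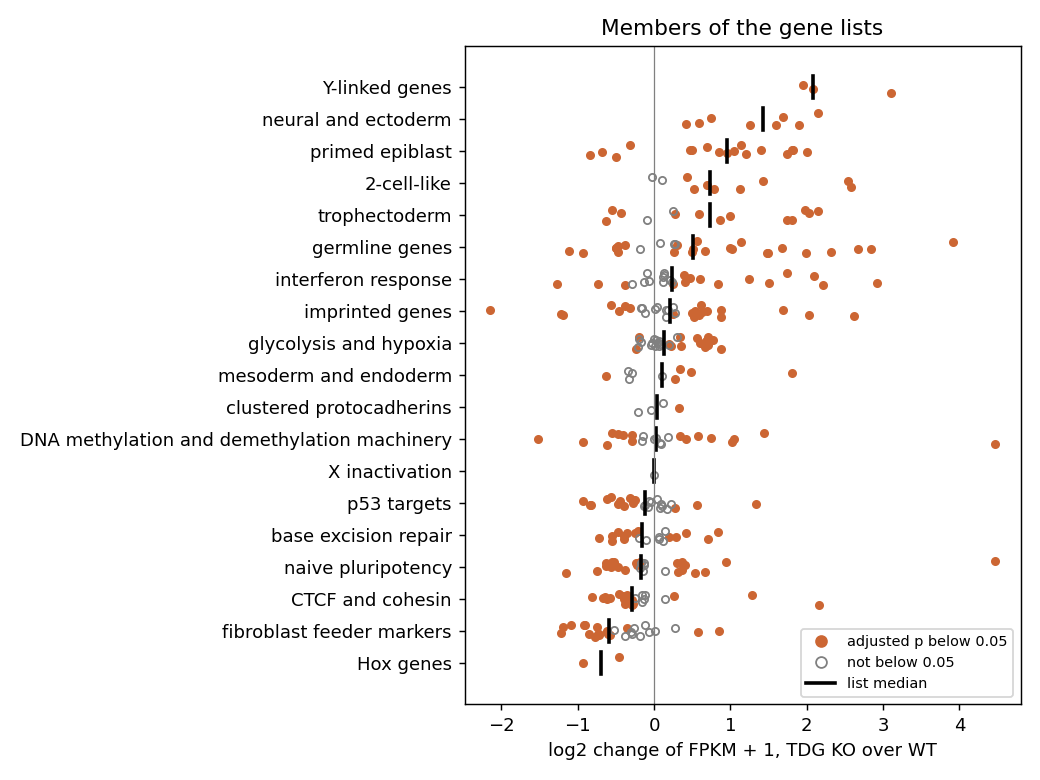
Each point is a tested member of a gene list, placed by its log2 change of FPKM + 1 in TDG KO over WT, filled where limma's adjusted p was below 0.05, and the bar is the list median. The 8 neural and ectoderm genes all lie above 0, and 16 of the 28 fibroblast markers fell.

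None of the 11 lists called by camera at the preset correlation was called with an estimated correlation. That test had 2 residual degrees of freedom, so correlation between genes need not be the reason. For neural and ectoderm genes the estimated correlation was -0.009, below the preset. Yet camera's unadjusted p went from 1.83e-06 to 0.0386. In other lists the estimate was higher, up to 0.904 for fibroblast markers. The lost calls therefore decide little about the lists. The authors' deposited table marks 4450 genes as significant, 2489 higher and 1961 lower in TDG KO. Of the 6496 genes called here 3422 are significant in the authors' deposited table, all in the same direction, and 3074 are not, among them Tubb3 (q-value 0.563), Apex1 (0.0657), Gm28625 (0.43) and Mir1957b (0.354). Tdg has a log2 change of -2.51 there with a q-value of 0.000468.

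The comparison of CTCF asks where binding differs without TDG. More CTCF peaks were listed in TDG KO: 48514 and 48833 in replicates 1 and 2, against 38303 and 37099 in WT. The means were 48674 ± 226 and 37701 ± 851 peaks (SD, n = 2), and the lists covered 15.0 ± 0.64 Mb in TDG KO and 10.3 ± 0.64 Mb in WT. Of the peaks of WT replicate 2, 96.7% lay in regions with a peak in TDG KO replicate 2, whereas 73.4% of the peaks of TDG KO replicate 2 lay in regions with a peak in WT replicate 2. Fewer peaks of WT replicate 2 lay in regions with a peak in WT replicate 1 (33394 of 37099) than in regions with a peak in the longer list of TDG KO replicate 2 (35893).

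The lists merged into regions of which 32740 were shared, 5885 were TDG KO-only and 93 were WT-only. Splits that mix the genotypes gave 233 and 242 exclusive regions (replicates 1 against replicates 2) and 430 and 390 (crossed numbers). With the strongest 37099 peaks of each list, 1245 regions were TDG KO-only and 724 WT-only, and the mixed splits gave 363 and 360, and 546 and 643. Leaving out a list moved the TDG KO-only count to 8952 without WT replicate 1, 9573 without TDG KO replicate 1 and 9453 without TDG KO replicate 2, and the WT-only count to between 186 and 1299.

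**Figure D3:**
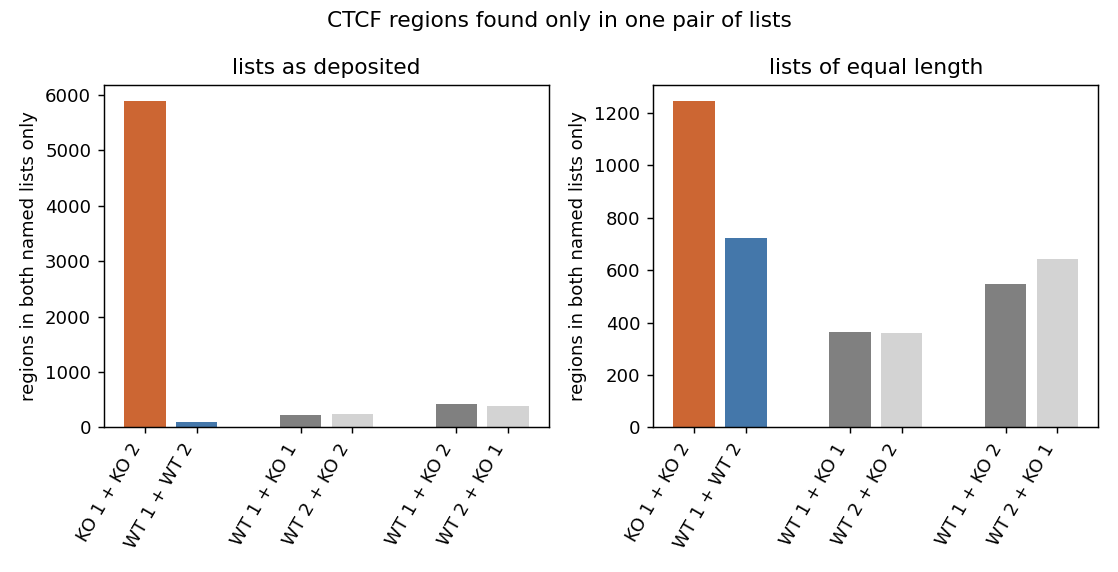
Bars count CTCF regions with a peak in both named lists and in neither of the others, for the lists as deposited (left) and for the strongest 37099 peaks of each list (right), on axes of different range. The 5885 TDG KO-only and 93 WT-only regions on the left become 1245 and 724 on the right.

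TDG KO-only regions were weak within their own lists. By the authors' score, their median percentile was 18.1 in TDG KO replicate 1 and 17.8 in TDG KO replicate 2, against 65.9 and 66.1 for shared regions. WT-only regions were weak too, with a median percentile of 13 in WT replicate 1 and 10 in WT replicate 2, against 56.8 and 55.3 for shared regions. A region must be missing from the lists of the other genotype to enter either class, which favours peaks near the threshold. The low ranks are therefore in part set by the class rule. Of TDG KO-only regions 11.5% (interval 10.7 to 12.3) were centred within 1 kb of a gene end, below the 14.7% (14.3 to 15.1) of shared regions, and WT-only regions stood at 11.8% (6.1 to 20.2). Inside genes beyond 1 kb lay 49.1% of TDG KO-only and 49.9% of shared regions.

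The best-ranked TDG KO-only regions were at chromosome 15, 97125754 to 97126184, between genes and 70013 bp from the amino acid transporter gene Slc38a4, at chromosome 11, 48750447 to 48750865, 49704 bp from Rack1, and at chromosome 16, 4979832 to 4980397, 6744 bp from Septin12. The best-ranked WT-only regions were at X, 159225162 to 159225799, 30184 bp from the kinase gene Rps6ka3, at chromosome 7, 30163225 to 30163469, inside Zfp146, and at X, 168935525 to 168935890, inside Arhgap6. The best-ranked shared regions were at chromosome 9, 72530196 to 72530607, inside 4930509E16Rik and 1768 bp from Rfx7, and inside Niban2 (chromosome 2, 32912235 to 32912834) and Ctif (chromosome 18, 75599561 to 75600387). Genes were named by the nearest protein-coding gene. Counting all genes, the region near Rack1 lay 953 bp from Gm12183 and that near Septin12 1152 bp from 4930451G09Rik. Of the 6 regions named for a single genotype 4 lie in shifted windows: those near Rack1 and Septin12 in higher windows, and those near Rps6ka3 and inside Arhgap6 in lower windows.

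At H19, an imprinted gene with CTCF sites in its control region, both regions within 10 kb were TDG KO-only, at chromosome 7, 142580196 to 142580947 and 142581683 to 142582144. H19 RNA was not called (log2 change -0.12, adjusted p = 0.592 in limma), nor was Igf2 (-0.15, adjusted p = 0.512). Like the fibroblast markers, both were higher in WT replicate 1 than in WT replicate 2, H19 at 119 and 79.6 FPKM and Igf2 at 53.1 and 35.5 FPKM. Near Pou5f1, a core pluripotency factor, 3 of 5 regions were TDG KO-only, near Nanog 2 of 6, near Rasgrf1 2 of 5, and near Peg3 and Myc 1 each. All TDG KO-only regions at these loci scored below the list medians of 33.9 and 35.1 in TDG KO replicates 1 and 2. Those at H19 scored 16.5 and 14.7 in replicate 1 and 20.7 and 11.7 in replicate 2. Their absence from the WT lists need not be a gain of binding. Nanog lies in a shifted window of chromosome 6. Of the other loci, 4 of 4 regions near Grb10 and 2 of 2 near Sox2 were shared, and no region lay within 10 kb of Tdg or Kcnq1ot1.

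Chromosome 11 stood apart in both measurements. It held 9.36% and 7.74% of the peaks in TDG KO replicates 1 and 2 and 6.32% and 7.21% in WT, and 890 of its 4668 regions (interval 17.9% to 20.2%) were TDG KO-only, against 8.5% to 14.6% on the other autosomes. The log2 ratio of its peak share, 0.34, fell to 0.19 without TDG KO replicate 1 and was 0.25 to 0.47 with another list left out, against at most 0.16 on the other autosomes. The median log2 RNA change of its 1028 tested genes was 0.37, with 84.9% above 0, against medians of -0.14 to 0.04 on the other autosomes. On the X chromosome from 160 to 170 Mb, 30 of 31 tested genes were lower (median log2 change -1.41), and on chromosome 16 up to 10 Mb 36 of 38 were higher (0.67). Outside the 28 shifted windows 4501 TDG KO-only and 43 WT-only regions were left (4254 to 5136 and 42 to 45 over the 15 window rules), and 5282 genes were called, 37.5% of them higher, by a limma fit without these windows. Of the genes called by the fit to all genes, 5227 to 5826 lay outside the windows over the 15 rules, with 37.5% to 41.2% higher. These windows were chosen after seeing the data. The shares also depend on the scaling, which was the same under all 15 rules. FPKM were not rescaled without the windows, and the median log2 change of the genes left was -0.08. Over all genes, upper-quartile scaling moved the share of higher calls from 45.3% to 49.8%.

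**Figure D4:**
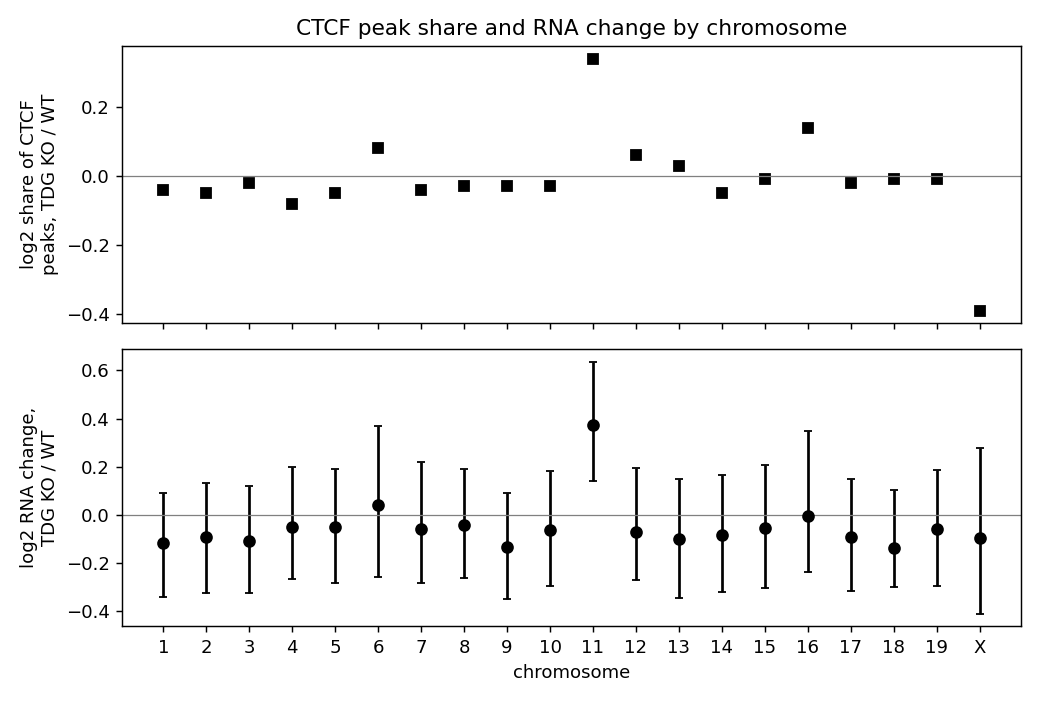
The upper panel gives the log2 ratio of the share of CTCF peaks, TDG KO over WT, for each chromosome, and the lower panel the median log2 RNA change with bars from the lower to the upper quartile of its genes. Chromosome 11 is highest in both, at 0.34 and 0.37, and chromosome Y is not drawn.

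Genes near TDG KO-only regions were compared with other genes to relate binding to RNA. Dppa3, Rhox5 and 1700019B21Rik were the highest called genes within 5 kb of such a region, and the transporter gene Slc38a5 (log2 change -1.79), the guidance cue Ntn1 (-1.45) and the noncoding RNA Malat1 (-1.33) the lowest. Of 944 genes with a TDG KO-only region within 5 kb of an end, 336 rose and 223 fell, and their median log2 change was 0.05 against -0.05 for other genes. Camera with an estimated correlation, as planned, did not set them apart (p = 0.116), while the preset correlation gave p = 0.0144. The estimate was 0.008, below the preset of 0.01, so correlation between genes did not raise the p-value. The planned test had 2 residual degrees of freedom, so its missing call decides little. With equal lists the medians were 0.31 for 165 such genes and -0.05 for others, 89 higher and 25 lower. Camera gave p = 0.0553 there with an estimated correlation and 2.37e-07 with the preset. With equal lists outside the shifted windows the medians differed by 0.03 (camera p = 0.36 with an estimated correlation, 0.381 with the preset). Outside the shifted windows the medians were -0.06 for 653 such genes and -0.08 for others (camera p = 0.624 with an estimated correlation, 0.633 with the preset). The 26 genes near WT-only regions had a median of -0.36 (camera p = 0.1 with an estimated correlation, 0.000184 with the preset). Outside the shifted windows the 14 left had a median of -0.13 against -0.08 (p = 0.376 with an estimated correlation, 0.213 with the preset). The 5593 genes near shared regions had a median of -0.01 (p = 0.412 with an estimated correlation).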

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

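The alternatives without the shifted windows, without chromosomes 11, X and Y, for protein-coding genes and for peak shares with a list left out were chosen after seeing the data, and the others before the data were examined. Tdg was lower under every alternative run (log2 change -2.49 to -1.76, limma adjusted p 2.37e-11 to 0.00263). The count of called genes stayed between 4819 and 6746 under all alternatives except the requirement of a log2 change of at least 1, which by its construction left 592 (435 higher and 157 lower). Leaving out a library gave 4819 to 5313, with the lone library of its group assumed to vary like the others. In the authors' deposited table a q-value below 0.01 left 2937 genes, and a log2 change of at least 1 left 1677. Of 11 lists called by camera, 6 were called with a mean FPKM of at least 5 and 0 with an estimated correlation. The latter had 2 residual degrees of freedom and hence little power. Fry, another planned list test in limma, also called 11 lists, but it asks another question. It tests the members without regard to other genes, where camera compares them with other genes, and 54% of all tested genes were called. It called DNA methylation and demethylation (fry adjusted p = 0.00325) and p53 targets (0.0445), which camera did not. It did not call CTCF and cohesin (fry adjusted p = 0.162) or fibroblast markers (0.273), which camera did. The replicate numbers did not pair the libraries: deviations of same-numbered RNA libraries correlated at -0.016, and the replicate block moved the calls from 6496 to 6696. Within a replicate number, 12241 (number 1) and 12960 (number 2) regions had a TDG KO and no WT peak, and 1905 and 1206 the reverse. With equal lists the ratio of peaks was 1.0 by construction, with 1245 TDG KO-only and 724 WT-only regions, and 852 and 541 with the shifted windows also left out. Without the shifted windows 43 WT-only regions were left, and 50 without chromosomes 11, X and Y. Leaving out a list gave 8328 to 9573 TDG KO-only and 186 to 1299 WT-only regions, since fewer lists then had to hold or lack a peak. The median percentile of TDG KO-only regions was 17.3 among the strongest 3 in 4 peaks, 13.8 in equal lists, 16.6 without the shifted windows, 16.5 without chromosomes 11, X and Y and 12.1 with equal lists and no shifted windows, and the cause was not tested. Within 5 kb of a gene end lay 35.8% of TDG KO-only, 32.3% of WT-only and 41.9% of shared regions, and 15.2% of shared regions lay within 1 kb among the strongest 3 in 4 peaks. No named gene or list reversed, but the excess of lower over higher calls turned with no filter (3345 higher and 2886 lower) and nearly vanished with upper-quartile scaling (3143 and 3165). All 28 shifted windows kept their direction whichever list was left out. The window rule, under which the genotypes could not overlap, largely fixed this in advance. Without WT replicate 1, 21 kept a log2 difference of at least 0.2. The motif comparison and its alternatives were not run for want of a genome sequence. Absolute depth is unknown for both assays, which limits what a peak missing from a list can show.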

Other observations

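Genes that rose strongly were unevenly spread over chromosomes. The X chromosome held 51 of the 435 genes that were called higher by at least 1 on the log2 scale (11.7%), and 3.7% of the tested genes, while its median log2 change was -0.10. It also held 38 of the 157 genes called lower by at least 1. On chromosome 6 from 100 to 130 Mb, 107 of 152 tested genes were called higher (median log2 change 0.41).

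The tests that weigh explanations in this part were chosen after the patterns were seen, while the lists of equal length, the log2 limit of 1 and the fibroblast list were fixed before the data were examined. Genotype and cell line are not separable in this design, so no test here addresses loss of TDG itself. Y chromosome peaks below 90 Mb numbered 2 and 2 in the WT lists and 31 and 55 in the TDG KO lists.

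Chromosome 11 was higher in TDG KO in both assays. For RNA, FPKM is already scaled by mapped fragments, so library depth would not set a single chromosome apart. The median log2 RNA change of chromosome 11 was 0.37 against at most 0.04 on any other autosome, which restates the pattern. Whether depth or enrichment shaped the peak share of chromosome 11 was not tested. TDG KO-only CTCF regions beside the genes are argued against by the 87 chromosome 11 genes with none within 100 kb, whose median was 0.33. That test does not cover stronger CTCF at regions also listed in WT. By the authors' score, shared regions of chromosome 11 had a median percentile of at least 79.5 in each TDG KO list. It was lower in both WT lists, and at most 69.8 on the other autosomes in the TDG KO lists. CTCF gained at shared regions beside the genes therefore stays open. A candidate explanation is an extra copy of the chromosome in part or all of the TDG KO cells. The lowest of the medians over 3 groups of chromosome 11 genes by mean FPKM was 0.33, above the highest of the other autosomes at 0.07. With 84.9% of chromosome 11 genes above 0, this largely restates the pattern and does not favour an extra copy over another chromosome-wide change. DNA copy number was not measured here, and the input libraries of the series, which would bear on it, were not analysed. A chromosome-wide change of another kind stays open. Beyond chromosome 11 a difference in copy number is left open. Off chromosome 11 RNA moved the way of the peaks in 9 of 15 shifted windows under the rule used, and over the 15 rules from 14 of 34 to 9 of 10.

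TDG KO-only regions outnumbered WT-only regions by 5885 to 93. Shifted windows do not account for this, since 4501 TDG KO-only regions lay outside them. Longer TDG KO lists, from depth or enrichment, cannot be told apart from a gain of weak sites: lists of equal length brought the ratio to 1.72, against at most 1.18 in the mixed splits, but trimming removes weak peaks whether or not they reflect a gain. Read counts at all regions in every library, and the input libraries, would bear on this.

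Fibroblast markers were lower in TDG KO RNA, which may reflect fewer feeder cells. Of the 18 called members 16 were lower and 2 higher, and all 28 were higher in WT replicate 1 than in WT replicate 2, so the share of feeder RNA may also differ between replicates. Stem cells may express some of these genes themselves. Vim and Tagln rose by 0.58 and 0.85, but the cells their RNA came from are not known. A smaller feeder share and a change in the stem cells therefore cannot be told apart here.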
